A study of Arabidopsis thaliana with 9 samples.

How the data were processed

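The series holds 9 chromatin immunoprecipitation sequencing (ChIP-seq) samples from whole Arabidopsis thaliana plants, 2 weeks old, strain Ws. In 3 groups of 3, plants carried GFP alone, GRF1 fused to GFP or GRF3 fused to GFP, each driven by the 35S promoter, a strong promoter active in most plant tissues. ChIP-seq recovers DNA bound by a protein with an antibody and sequences it. Here the antibody was against GFP (5 mg/ml stock), per the labels. The 3 samples with GFP alone had no peak list here and were not analysed here.

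Each of the other 6 samples came with 1 list of peaks, so peaks had been called per library and not on pooled replicates. FastQC, Trimmomatic, Bowtie2 and MACS2 and the genome build TAIR10 are named in the submitters' processing notes, without versions, settings or the role of each. The control that the peak caller was given is not given in the sources used here. The deposited lists give, for each peak, its position, summit, a score, a fold enrichment over the control (a ratio), and the −log10 of a p-value and of a q-value. The authors' deposited score was, in all 6 lists, the whole-number part of 10 times the −log10 of the q-value. Fold and −log10 q are the authors' own values and were used only to describe, rank or filter peaks inside a list. No list gives a read count, so the sequencing depth of each library is unknown and no interval that needs depth was computed. All 14913 peaks lay on chromosomes 1 to 5, with 0 on organelle chromosomes.

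A consensus region of a factor was a run of peaks overlapping by at least 1 bp and found in at least 2 of its 3 libraries. Its summit was the median of the libraries' summits. GRF1 and GRF3 consensus regions were compared by overlap of at least 1 bp, against 1000 random placements of the smaller set on the same chromosomes (seed 7). Agreement between libraries was measured by the Jaccard index, the bases shared by 2 lists divided by the bases in either. Differences between the factors were tested over the 6 libraries with exact permutation tests, which cannot go below p = 0.1 with 3 against 3.

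Genes came from a RefSeq table of assembly TAIR10.1, used for names and for which genes lie near a region. It holds gene spans but no strand, exons or UTRs, so the planned classes (promoter, exon, intron, UTR) and the planned target rule based on the transcription start could not be made. In their place, a summit was put inside a protein-coding gene span, within 1 kb outside it, or farther away. A target gene was 1 of 27444 protein-coding genes with a summit inside its span or within 1 kb of it. All printed coordinates are those of the files (TAIR10, counted from 1). An offset between both coordinate systems would move the distances left and right of genes in opposite directions. Among all summits within 1 kb outside a span, the fullest 20 bp bin was 280 to 300 bp on either side for both factors. On single chromosomes its start ran from 140 to 280 bp on the left and from 240 to 280 bp on the right, with as few as 4 summits in it.

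The 30 gene lists were written before the data were examined and matched on gene symbols, and for some lists on product names among the synonyms. 1 list had no member and was not tested. The other lists were tested with Fisher's exact test, two-sided, for each factor, and the 58 p-values were adjusted together (Benjamini-Hochberg, threshold 0.05). A symbol can be shared by unrelated genes: EPR1 names both a clock gene and an extensin. Reading the gene table's synonyms, after the data were seen and whether or not a gene was a target, found 41 such members in 15 lists; they stay in the main counts. GRF1 and GRF3 targets were compared per list with an exact binomial test on genes targeted by 1 factor only. Named genes followed a rule fixed beforehand: the nearest target gene of the 12 regions of each factor highest in the libraries' fold ranks and found in all 3 libraries, every GRF, GIF and miR396 gene, and members of lists past the threshold. Other named genes were chosen after their values were seen.

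Alternatives set beforehand were a −log10 q of at least 5, a fold of at least 4, regions in all 3 libraries, lists reduced to the length of the shortest (1122 peaks), reciprocal overlap of 50%, summits within 100 bp, another agreement measure, a placement-matched background, a replicate block and leaving out each library. Not all of these were planned for every result: leaving out each library was added afterwards for the overlap of target genes, replicate agreement, the lists compared between factors and the regions of 1 factor only, equal-length lists for the overlap of target genes, and the −log10 q and all-library settings for the lists compared between factors. Also chosen after seeing the data were targets within 500 bp or 3 kb of a span, placement near genes, 20000 matched placements, matching on synonyms, the clock list without the extensin, all lists without the 41 members, and runs without regions of 3 kinds: summits 280 to 310 bp outside a span, narrow peaks with a summit near an edge, and gene-poor 100 kb windows. Sequence motif tests needed a genome and were not run. The tests were checked on simulated data. With unrelated sets, 1 of 100 overlap tests and 5 of 100 position tests gave p under 0.05. With 300 regions shared, an excess of 298.2 was recovered. All 20 seeded gene lists were called, with 1 of 80 unseeded ones, over 27444 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.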

Results

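Growth-regulating factors (GRFs) are plant transcription factors best known for promoting leaf growth, and they act with GIF coactivators and are repressed by the microRNA miR396. The series asks where in the genome 2 of them, GRF1 and GRF3, bind. The data analysed were peak lists of 3 35S:GRF1-GFP and 3 35S:GRF3-GFP libraries from whole plants. The labels describe a planting in replicate blocks but do not say whether replicates were processed separately. P-values of the permutation tests over libraries therefore measure only the spread between these libraries. All other p-values come from random positions or from counting genes or regions, and measure no spread between libraries.

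GRF3-GFP libraries had more and GRF1-GFP libraries fewer peaks, spread over all 5 chromosomes. The GRF1 libraries held 1410, 1122 and 1878 peaks (1470 ± 382, SD, n = 3) and the GRF3 libraries 2258, 2301 and 5944 (3501 ± 2116, SD, n = 3). The lowest GRF3 library was above the highest GRF1 library, and the mean difference was 2031 peaks (exact permutation test, two-sided, p = 0.1, the smallest this design allows). GRF3 replicate 3 held most of the excess: without it the difference was 809.5 peaks. Among peaks with a fold of at least 4, the means were 509 ± 195 for GRF1 and 582 ± 121 for GRF3 (SD, n = 3; exact permutation p = 0.7), so the factors differed by less than the spread between libraries. Median fold was 2.43, 4.52 and 2.60 in the GRF1 libraries and 2.41, 2.44 and 2.56 in the GRF3 libraries.

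**Figure D1:**
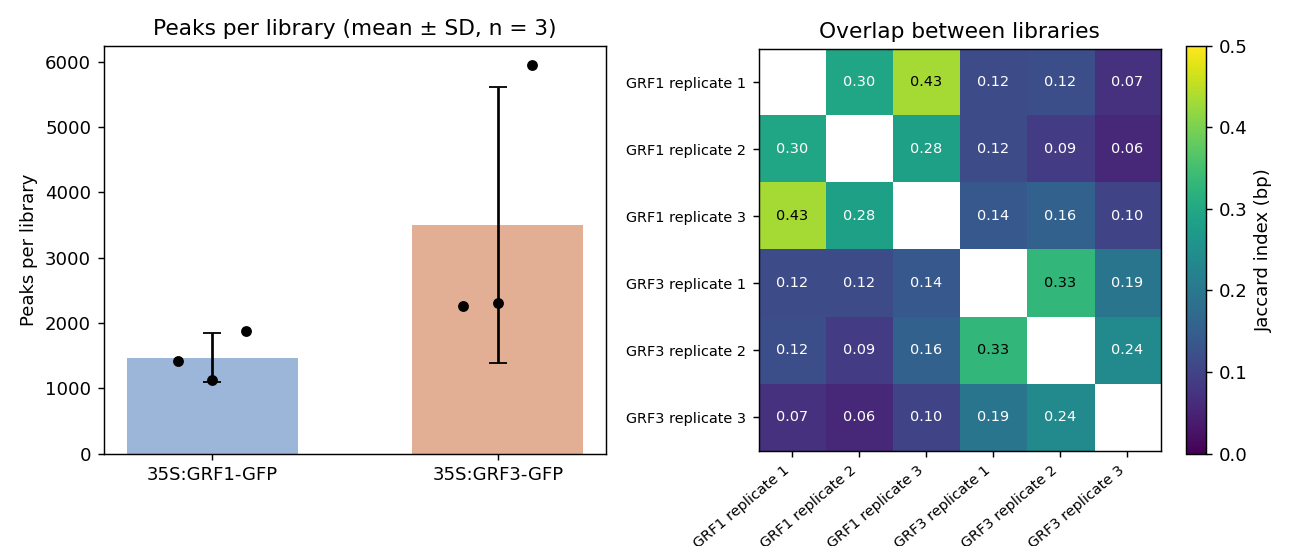
Left, peaks per library (vertical axis, points) with the mean and SD of each factor (bars, n = 3); right, Jaccard index between each pair of the 6 libraries. GRF3 replicate 3, with 5944 peaks, lies far above the others, and indices within a factor (0.194 to 0.433) exceed those between factors (0.058 to 0.156).

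GRF1 had 1147 consensus regions and GRF3 had 2203. The series' design text states 1108 and 2194. Of the GRF1 regions, 588 were in all 3 libraries and 559 in 2, and of the GRF3 regions 960 and 1243. Of the 559, 419 were in replicates 1 and 3 only, 100 in replicates 2 and 3 and 40 in replicates 1 and 2. Many of the 419 lay close together on chromosome 1, mostly with no gene within 1 kb. There the folds were mostly below the median folds of replicates 1 and 3 (2.43 and 2.60). Of the 1243, 681 were in replicates 2 and 3 only, 438 in replicates 1 and 3 and 124 in replicates 1 and 2. Regions seen in 1 library only numbered 1488 for GRF1 and 5005 for GRF3. The GRF3 count rested in part on replicate 3, since the other libraries shared 1100 regions. For GRF1, 634 regions were left without replicate 3 and 688 without replicate 1. For GRF3, 1397 were left without replicate 2. GRF1 replicate 2 stood apart in where its peaks lay: 82.8% of its summits were inside or within 1 kb of a protein-coding gene, against 46.0% and 45.4% in replicates 1 and 3.

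Libraries of the same factor shared more sequence than libraries of different factors. The Jaccard index averaged 0.337 within GRF1, 0.254 within GRF3 and 0.107 between the factors. Each of the 6 indices within a factor was above each of the 9 between factors (difference of means 0.189, exact permutation test over the 10 splits, one-sided, p = 0.1, the smallest possible). Across all 6 libraries, 162 merged regions were found in every library. In all 3 libraries of 1 factor and none of the other there were 899 regions, 310 for GRF1 and 589 for GRF3. Without GRF3 replicate 1 that total was 1452, but a region then needed only the remaining GRF3 libraries, which raises the count by construction.

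The tagged factors' own genes carried peaks in their own libraries. At GRF1 (AT2G22840, chromosome 2), the GRF1 libraries had 3 consensus regions inside the gene span: 9728316 to 9729544, fold 2.64 ± 0.39; 9729790 to 9730162, fold 2.99 ± 0.34; and 9730502 to 9731138, fold 2.61 ± 0.23 (SD, n = 3 each). At GRF3 (AT2G36400, chromosome 2), the GRF3 libraries had 2: 15270300 to 15270737, fold 12.6 ± 3.1, and 15271545 to 15272636, fold 11.3 ± 2.6 (SD, n = 3 each). No GRF1 library had a peak at GRF3, while GRF3 replicate 3 had 2 peaks at GRF1, with folds of 2.34 and 1.93. Both, at 9729828 to 9730133 and 9730598 to 9731011, lay inside the second and the third of the GRF1 libraries' regions. Some edges were the same in all 3 libraries, as 9729790 and 9731138 at GRF1 and 15270300 at GRF3. The first GRF1 region differed: it started at 9728841 in replicate 1 and at 9728316 in replicate 2, and replicate 3 had 2 peaks there, 9728350 to 9728593 and 9728841 to 9729528.

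Elsewhere in the GRF, GIF and miR396 genes, GRF7 (AT5G53660, chromosome 5, 21794074 to 21794452) had a GRF1 region inside its span in all 3 libraries, fold 4.70 ± 1.45 (SD, n = 3). GRF4 had a peak in GRF1 replicate 3 only (fold 3.64) and GRF8 in GRF1 replicate 2 only (fold 3.55). The other members, GRF2, GRF5, GRF6, GRF9, the coactivator genes GIF2, GIF3 and AN3, MIR396a and MIR396b, had no peak in any of the 6 lists. In all, 11 of 14 members had no consensus region of either factor. Among the 12 protein-coding members, 2 were GRF1 targets (odds ratio 6.23, Fisher's exact p = 0.052, adjusted p = 0.754) and 1 was a GRF3 target (adjusted p = 0.925), neither past the threshold. The GRF1 targets were GRF1 itself and GRF7, and the GRF3 target was GRF3 itself. Peaks at a tagged factor's own gene may come from transgene DNA rather than binding.

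**Figure D2:**
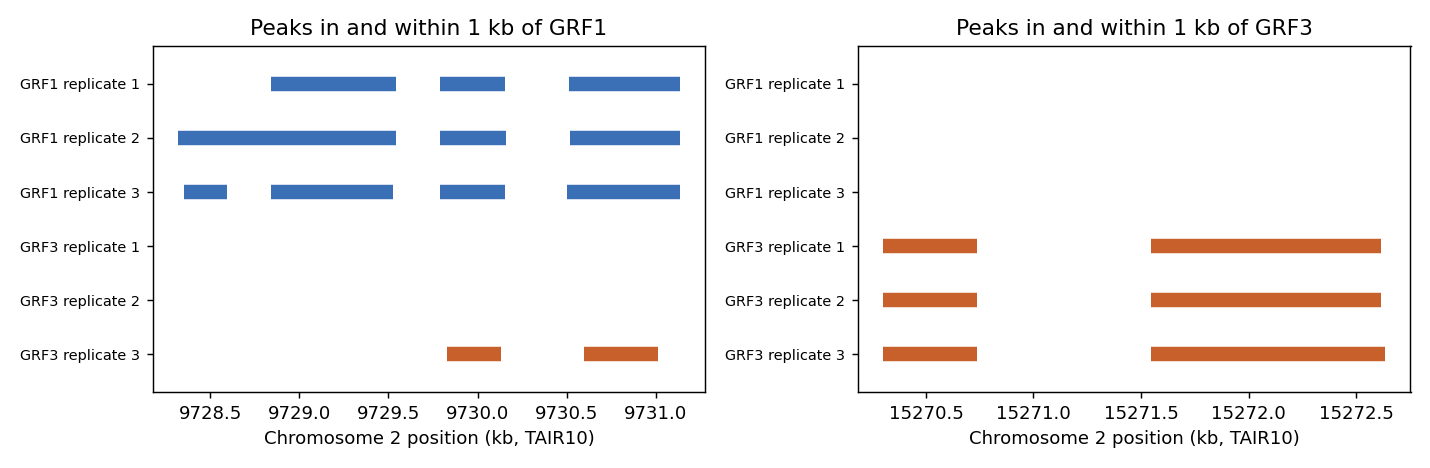
Peaks (bars) of each of the 6 libraries in and within 1 kb of GRF1 (left) and GRF3 (right), by position on chromosome 2 in kb. At GRF3 the bars of its own libraries have nearly the same ends, for example 15270300 and 15270737; at GRF1 the first block starts at 9728841, 9728316 and 9728350 and is split in replicate 3.

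The regions with the highest fold ranks were largely common to both factors. Of the 12 highest of each, 6 overlapped. They lay near AT5G37240 (chromosome 5, 14739571 to 14739875; GRF1 fold 106 ± 26, GRF3 fold 44.8 ± 15.4), at AGL14, a MADS-box gene (chromosome 4, 7146447 to 7146731; 50.8 ± 8.8 for GRF1, and 37.3, 18.8 and 27.9 in the GRF3 libraries), at SECA2 (chromosome 1; 52.3 ± 12.7 and 25.2 ± 10.4), near AT1G13230 (69.1 ± 16.1 and 23.7 ± 8.7), at UGT73C2, a glycosyltransferase gene (54.7 ± 12.9 and 22.4 ± 7.6), and at chromosome 5, 24022828 to 24023156, with no gene within 1 kb (52.6 ± 18.9 and 46.0 ± 14.0; SD, n = 3 throughout). The other GRF1 regions lay at or near AT2G34317, AT5G22799, ALPHA DOX2, AT4G32700, AT5G47540 and chromosome 4, 4547832 to 4548209. The other GRF3 regions lay at or near AT3G23460, AT1G27880, AT3G50180, OVA2 and, with no gene within 1 kb, chromosome 3, 11895339 to 11895619 and 10938226 to 10938498. OVA2 (chromosome 5, 19882988 to 19883878, fold 25.2 ± 3.2, SD, n = 3) was the single GRF3 region of the 12 that overlapped no GRF1 region. In 9 of the 12 regions of each factor, the summit lay in the first or last 25% of the peak's width; such regions that were also narrow numbered 7 for GRF1 and 0 for GRF3.

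GRF1 and GRF3 regions overlapped far more often than random placement gave. Of the 1147 GRF1 regions, 386 (33.7%, 95% exact interval 30.9 to 36.5, counting error only) overlapped a GRF3 region, against 21.7 ± 4.6 (SD over 1000 placements) at random, one-sided p = 0.001, the smallest these placements give. From the GRF3 side, 384 of 2203 regions (17.4%) overlapped. A control common to both sets of libraries would also give shared regions; which control was used is not given, so part of the excess may come from it.

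Consensus summits of both factors lay inside protein-coding genes less often than positions placed at random over whole chromosomes. For GRF1 303 of 1147 summits (26.4%, against 54.0% at random) and for GRF3 754 of 2203 (34.2%, against 53.8%) were inside a gene span, both with p = 0.002 in a two-sided permutation test of positions (1000 random placements), the smallest possible. Outside genes but within 1 kb lay 331 GRF1 summits (28.9%, against 20.5%) and 425 GRF3 summits (19.3%, against 20.4%). Beyond 1 kb lay 44.7% and 46.5%, against 25.5% and 25.8%. Gene-poor 100 kb windows, 16.3% of all windows, held 42.6% of GRF1 and 43.4% of GRF3 summits. Without these windows the shares inside genes were 41.9% for GRF1, against 62.3% at random in the other windows, and 56.4% for GRF3, against 62.5% (permutation test of positions, p = 0.002 for both). Positions 500 bp to the left or right of the summits were inside genes in 32.3% and 40.6% for GRF1 and 38.4% and 38.7% for GRF3, and positions 5000 bp away in 36.2% and 37.0% for GRF1 and 33.9% and 35.2% for GRF3. The GRF3 share at the summits (34.2%) was thus close to that 5000 bp away and below that 500 bp away. Most of its shortfall against random positions was therefore shared by the surroundings. The GRF1 share (26.4%) was below that of its surroundings at either distance. Over all peaks of single libraries the share was 23.3%, 51.9% and 23.8% for GRF1 and 49.9%, 33.4% and 47.2% for GRF3 (means 33.0% ± 16.3 and 43.5% ± 8.8, SD, n = 3), so the shortfall was smaller in GRF1 replicate 2 and GRF3 replicates 1 and 3. Whether a summit was in an exon, intron or UTR was not assigned.

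Summits near genes were not spread evenly. Within 320 bp outside a gene span lay 270 GRF1 and 341 GRF3 summits, and in the next 320 bp outward 35 and 41. Between 280 and 310 bp there were 70 GRF1 regions, against 8.39 ± 2.92 at random, and 116 GRF3 regions, against 15.8 ± 3.9 (SD over placements). Of these, 58 and 114 were in all 3 libraries. Their folds were close together. The median was 4.42 for GRF1, most lying between 3.99 and 5.12, against 3.96 for other GRF1 regions. For GRF3 it was 9.34, most lying between 6.95 and 10.5, against 2.58 for other GRF3 regions. Examples, chosen after their values were seen, were the response regulator gene RR2 (GRF1, 300 bp, fold 4.29 ± 1.87) and, for GRF3, the cytokinin synthesis gene IPT4 (300 bp, fold 7.32 ± 0.87) and ERD2 (287 bp, fold 7.25 ± 0.46; SD, n = 3 each). Such GRF3 folds were not particular to this band. Regions outside it with similar folds, also chosen afterwards, were at CCS52A2 (254 bp, 9.99 ± 0.84), LHCB2.1 (246 bp, 10.3 ± 1.4) and SOS3 (209 bp, 10.1 ± 0.6). Another lay inside the span of LHY (9.95 ± 1.71, SD, n = 3 each).

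**Figure D3:**
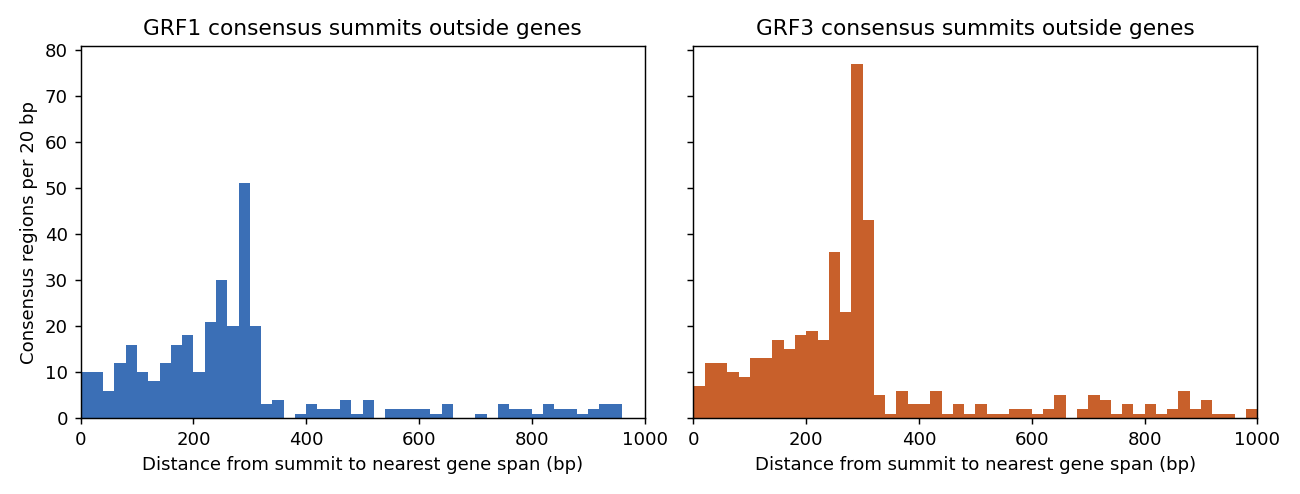
Consensus regions per 20 bp (vertical axis) by distance in bp from the summit to the nearest protein-coding gene span, for GRF1 (left) and GRF3 (right), summits outside genes only. Both fill up to about 320 bp, with 70 GRF1 and 116 GRF3 regions between 280 and 310 bp, and few beyond.

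These regions gave 855 target genes for GRF1 (3.12% of 27444) and 1516 for GRF3 (5.52%). Both factors had 249 of them in common, where independent lists of these sizes would share 47.2 (odds ratio 8.21, Fisher's exact test, p = 5.88e-113, genes not being independent). Over the alternatives the odds ratio ran from 5.79, with genes within 3 kb, to 12.9 at −log10 q of at least 5 and 13.02 with lists of equal length. Shared targets included AGL14, ARF19, ARF14, CCS52A2, CDC20.5 and CRF1, chosen after their values were seen. The caution on a common control holds here too. Without GRF3 replicate 3 there were 929 GRF3 targets.

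Of the 29 gene lists tested, the circadian clock list passed for GRF3 and none passed for GRF1. GRF3 targets held 8 of 30 clock genes (26.7%, against 5.52% of all genes; odds ratio 6.25, Fisher's exact test, adjusted p = 0.00968). These were LHY, a core morning gene of the clock (chromosome 1, 33204 to 33628, fold 9.95 ± 1.71, SD, n = 3), LKP2, a light-sensing F-box gene (fold 9.49 ± 0.77 at chromosome 2, 8194383 to 8195661, SD, n = 3), TOC1, a core evening gene (fold 2.22 ± 0.08, SD, n = 3), EPR1 (2.21 ± 0.21, SD, n = 3), and, with regions in 2 libraries only, ELF3, TIC, CDF3 and PRR3, at mean folds of 2.24, 2.80 and 2.00 (2 regions), 2.17 and 1.98. Summits of 7 of the 8 lay inside the gene span, and that of PRR3 was 937 bp outside. The folds given for LHY and LKP2 lay between 6.95 and 10.5, as did those of most GRF3 regions 280 to 310 bp outside genes. The source of those regions is open, and whether LHY and LKP2 share it was not tested. ELF3 alone was also a GRF1 target. The EPR1 region was in the extensin gene of that symbol (AT2G27380), not the clock gene: without it the list held 7 of 29 (odds ratio 5.46, Fisher's exact test, adjusted p = 0.0478), and without all 6 members that share a symbol with another function 7 of 24 (odds ratio 7.07, adjusted p = 0.0135). The call was lost in 8 alternatives (Fisher's exact tests, and a permutation of positions for the placement-matched background): with a −log10 q of at least 5 and with lists of equal length (adjusted p = 1 in both), with regions in all 3 libraries (0.621), with synonyms (0.0921), with a placement-matched background of 20000 placements (0.0638, 4.17 times the random mean), and without GRF3 replicate 1, 2 or 3 (0.338, 0.0828 and 0.955, with odds ratios of 4.91, 5.66 and 4.41). The planned 1000 placements could not give an adjusted p below 0.116 for a single list, so they decide nothing. The 7 alternatives in which the call held were all chosen after seeing the data, and every planned one that could pass lost it. GRF1 and GRF3 targets did not differ in this list past the threshold (7 genes of GRF3 only, 0 of GRF1 only, exact binomial p = 0.105, adjusted p = 0.752).

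Of the other lists none passed for either factor. Heat shock genes had 9 of 63 members among GRF3 targets, 3.48 being expected (odds ratio 2.86, Fisher's exact p = 0.00748, adjusted p = 0.217), among them Hsp70b (fold 8.78 ± 0.71 and 7.40 ± 0.69 in 2 regions), mtHsc70-1 (9.53 ± 1.27) and ERD2. Core cell cycle genes had 8 of 77 for GRF3 (Fisher's exact test, adjusted p = 0.791), with CDC20.2 (fold 10.6 ± 1.0) and CCS52A2 (9.99 ± 0.84), and 5 of 77 for GRF1, with the cyclin genes CYCB1;4 (4.36 ± 1.06) and CYCB2;2 (4.55 ± 1.33; SD, n = 3 throughout). Cytokinin genes had 6 of 77 for GRF1 (odds ratio 2.64, Fisher's exact p = 0.0329, adjusted p = 0.637), HK1, LOG1, IPT7, ARR9, CRF1 and RR2, and 5 of 77 for GRF3. Light signalling had 7 of 72 for GRF3 (Fisher's exact test, adjusted p = 0.791) and 3 of 72 for GRF1. The highest GRF3 folds of this list were at FRS5 (9.06 ± 0.71) and FRS6 (7.55 ± 0.95, SD, n = 3 each). PIF4, PIL1, PIL5 and PIL6 had mean folds of 2.67, 2.18, 2.09 and 2.06, all but PIL1 with regions in 2 libraries only. The GRF3 folds given for Hsp70b, mtHsc70-1, CCS52A2, FRS5 and FRS6 lay between 6.95 and 10.5, and that of CDC20.2 just above. Most GRF3 regions 280 to 310 bp outside genes had folds in that range, and a common source was not tested.

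Auxin genes had 7 of 137 GRF1 and 10 of 137 GRF3 targets, and flowering genes 5 and 4 of 117. Meristem and leaf development genes had 5 and 8 of 203. Abscisic acid genes had 2 and 4 of 62, jasmonate 2 and 2 of 45, ethylene 2 and 3 of 70, gibberellin 0 and 2 of 37, brassinosteroid 0 and 2 of 47, and salicylate and immunity 1 and 3 of 92. Cold, drought and salt genes had 2 and 4 of 83, and nuclear photosynthesis genes 1 and 3 of 59, the 1 for GRF1 being PSAT (AT4G35630), a phosphoserine aminotransferase gene matched by symbol only. WRKY genes had 3 and 5 of 67, MYB genes 5 and 5 of 131, NAC genes 3 and 2 of 103, bZIP genes 3 and 2 of 51, bHLH genes 0 and 0 of 31, TCP genes 0 and 1 of 17, and CO-like, DOF and GATA zinc finger genes 0 and 6 of 66. Cell wall genes had 1 and 7 of 139, the 7 including CARB (AT1G29900), a carbamoyl phosphate synthetase gene, and CAB1 (AT1G29930), a chlorophyll-binding protein gene, both matched on a synonym. Glucosinolate and flavonoid genes had 3 and 6 of 71, with the phosphatase gene PAP9 (AT2G03450) in both counts, histones 2 and 1 of 31, SWI/SNF remodelling genes 3 and 1 of 58, and cytosolic ribosomal proteins 1 and 0 of 53. The heat shock list for GRF1 held 1 of 63. Over the 29 lists, 1 had an unadjusted p under 0.05 for GRF1 and 2 for GRF3. None differed between the factors (exact binomial test, lowest adjusted p = 0.752).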

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

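Chosen after seeing the data were the distances of 500 bp and 3 kb, synonyms, the lists without shared symbols, placement near genes, the runs without regions of 3 kinds, equal lists for the overlap of target genes, −log10 q and all 3 libraries for the lists compared between factors, and leaving out libraries for these 2 results, agreement and regions of 1 factor only. Under all alternatives run, the overlap of regions, the overlap of target genes (odds ratio 5.79 to 13.02), the share of summits inside genes below that of random positions, the excess of agreement within factors and the lack of called lists for GRF1 stayed on the same side of their thresholds. The overlap of regions, a share of the smaller set, ran from 25.9% to 37.7% with a library left out. The smaller set was GRF3 at 25.9%, without GRF3 replicate 3, and GRF1 otherwise. Summits inside genes ran from 20.04% to 41.9% for GRF1 and from 21.0% to 56.4% for GRF3. Both were highest without gene-poor windows, against 62.3% and 62.5% at random there. For GRF3 positions 5000 bp from the summits had a similar share in the main run. The 2 permutation comparisons of 3 against 3 could not pass their thresholds, so their calls could not change. The peak number difference of 2031 came to 650 at −log10 q of at least 5 and to 73.3 at a fold of at least 4. The cause of the changes below was not tested, except that stricter choices keep fewer peaks by construction. Leaving out a library also changes the rule. Consensus regions then need every remaining library of the factor, so their number falls by construction. Regions of 1 factor only need fewer libraries, so their number rises by construction.

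GRF1 consensus regions fell to 588 in all 3 libraries and to 658 without gene-poor windows, and ran from 634 to 1007 with a library left out. GRF3 regions came to 1258 at −log10 q of at least 5, 960 in all 3 libraries, 948 with lists of equal length and 1248 without gene-poor windows, and from 1100 to 1643 with a library left out. GRF3 targets came to 904, 829 and 820 under the first 3 of these, 2553 within 3 kb, and from 929 to 1165 with a library left out; GRF1 targets came to 1454 within 3 kb. Regions of 1 factor only ran from 968 to 1452 with a library left out.

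The number of lists passing for GRF3 was 1, and 0 at −log10 q of at least 5, in all 3 libraries, with equal lists, with synonyms, with 20000 matched placements (added afterwards) and without any 1 GRF3 library (0 to 0; odds ratio of the clock list 4.41 to 5.66, against 6.25 in the main run). It was also 0 with the planned 1000 matched placements, which could not pass for a single list (lowest adjusted p 0.116). For the clock list the odds ratio was 3.27, 4.96, 2.32 and 4.16 in the first 4 and 4.17 times the random mean in the next, and it stayed past the threshold only in 7 alternatives, all chosen after seeing the data.

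The replicate block, an exact sign-flip permutation, gave p = 0.25 for the 2031 peak difference, the smallest 3 pairs allow. Same-numbered GRF1 and GRF3 libraries shared no more than others (Jaccard 0.102 against 0.110, exact permutation p = 0.833), and 1 of 6 libraries was closest to its own number, so the numbers were not treated as pairs. Organelle peaks were absent, so that alternative gave no value. Motif, 6-mer and transcription start alternatives were not run. Sequencing depth is unknown, so whether an absent peak reflects depth cannot be said.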

Other observations

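Tests in this part were chosen after the patterns had been seen, and what each explanation predicts was written down after that; the count of regions in all 3 libraries of 1 factor and none of the other, and its comparison with other splits, were planned.

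GRF3 summits lay inside annotated pseudogenes, a class that is common in gene-poor chromosome regions, far more often than random positions: 762 of 2203 (34.6%, 95% exact interval 32.6 to 36.6), against 8.997% at random (placement p = 0.002, two-sided, the smallest possible). For GRF1 the count was 156 of 1147 (13.6%), against 8.76%. Per library the share was 16.1% ± 10.04 for GRF1 and 29.95% ± 7.76 for GRF3 (SD, n = 3, exact permutation p = 0.2, where 0.1 is the smallest possible). GRF1 replicate 3, at 25.3%, was above GRF3 replicate 1, at 21.0%. The peaks with the highest −log10 q in the GRF3 libraries were all near chromosome 3, position 14191805, with folds of 5.10, 4.97 and 6.94.

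Over 95 groups of genes that share a symbol stem and have at least 15 members, 3 of 190 tests passed. Auxin response factor genes held 7 GRF1 targets of 23 (odds ratio 13.7, Fisher's exact test, adjusted p = 0.000837). These were ARF2 on chromosome 5, and on chromosome 1 ARF14 (fold 22.5, 14.3 and 26.5 in the 3 libraries), ARF15, ARF19, ARF21, ARF22 and ARF23. ARF2, ARF15 and ARF21 had regions in 2 libraries only. The regions of ARF22, ARF21, ARF15 and ARF14 lay between 12556255 and 13109203 of chromosome 1, and the test counts such neighbours as independent genes. CHX cation exchanger genes held 8 GRF3 targets of 23 (odds ratio 9.16, Fisher's exact test, adjusted p = 0.00188), such as CHX20, CHX24 and CHX27. MEE genes, named for a mutant screen and not related in sequence, held 7 GRF1 targets of 44 (odds ratio 5.92, Fisher's exact test, adjusted p = 0.0247). No alternative setting was run for any of these groups.

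Summits clustered about 300 bp outside gene spans. Chance placement over whole chromosomes is argued against: the band held at least 7.35 times the random mean in both factors, and its fullest bin exceeded that of all 1000 placements. These placements were not kept near genes. GRF1 summits were more frequent within 1 kb outside genes than random positions (28.9% against 20.5%), which raises the GRF1 ratio. For GRF3 these shares were 19.3% and 20.4%. A single DNA contaminant common to all libraries is argued against too, since a GRF1 and a GRF3 library shared at most 12.2% of the gene ends involved, against 72.0% to 88.7% within a factor. Binding should not depend on which chromosome side of a gene a site is on, yet GRF3 regions on the right had a mean log2 fold 0.37 higher than those on the left (permutation p = 0.0001, the smallest possible; higher in 3 of 3 libraries), while for GRF1 the difference was 0.05 (p = 0.526), which decides nothing. A contaminant specific to each factor's libraries, or binding at a set distance from coding sequences with a side effect of processing, may remain, and neither was tested.

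Peaks over the tagged factor's own gene may come from DNA of the transgene rather than from binding, and such DNA would give edges that agree closely between libraries. That was so for GRF1 regions 2 and 3 in order of position (only 1.19% and 3.56% of the other GRF1 regions in 3 libraries were as sharp) and for GRF3 region 1 (0.111%), while GRF3 region 2 (5.87%) decides nothing. GRF1 region 1, where 95.7% were as sharp (82.2% for the mean of the 3 regions), decides nothing either, since the peak of replicate 3 is split there and the range depends on which pieces were called. The shared edges had prompted this test, and its rule was changed 3 times after values were seen, also after the mean and region 1 had gone against transgene DNA, so it carries little weight. Exon positions were not used and carry-over between libraries was not tested, so these and binding of a factor to its own gene stay open.

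Narrow peaks whose summit lay near the left edge made up 248 of 249 narrow edge-summit regions of GRF1 and 89 of 93 of GRF3, where a symmetric shape would give equal sides. A background common to both factors' libraries may account for them in GRF3, where they overlapped the other factor more often than other regions did (47.3% against 16.1%, odds ratio 4.67, Fisher's exact p = 9.05e-12). In GRF1 the odds ratio was 0.959 (Fisher's exact p = 0.82), which leaves this open. In GRF1 their median fold was 9.65, against 2.89 for other regions, and they made up 27 of the 50 regions with the highest fold ranks. In GRF3 the folds were 3.37 and 2.61, and they made up 3 of 50. The width cut for narrow was lower in the GRF3 libraries, so these counts, folds and odds ratios cannot be compared directly between the factors.

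The 899 regions found in all 3 libraries of 1 factor and in none of the other compare with at most 89 in any other split of the 6 libraries. Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.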
